A study of Homo sapiens with 30 samples.

How the data were processed

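HepG2, an established human hepatocellular carcinoma line, was infected with lentiviral short hairpin RNAs against IGF2BP1, IGF2BP2 or IGF2BP3 or with a non-specific control hairpin (shNS), and stable lines were selected with puromycin, per the labels' protocols. The 30 RNA sequencing libraries fall into 12 from untreated cells, 3 for each of the 4 lines, and 18 from cells treated with actinomycin D, an inhibitor of transcription, at 5 µg/mL. The treated libraries cover shNS, shIGF2BP1 and shIGF2BP3 at 1, 3 and 6 h, with 2 libraries per line and time point. Half-lives of shIGF2BP2 were not analysed here. Total RNA was extracted with a miRNeasy kit, external ERCC transcripts were added, and directional libraries were made, per the labels' protocols. FastQC 0.11.4, HISAT2 2.0.4 and HTSeq were used with human genome build hg19, per the submitters' processing notes, which give no version for HTSeq. Because the files are in build hg19 and the reference annotation used here is in a later build, no coordinates are given.

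The deposited expression table holds RPKM (reads per kilobase of transcript, scaled to mapped reads), as 1 average by the authors for each of the 4 untreated lines and 18237 genes. Its columns sum to 377072 RPKM in shNS, 355095 in shIGF2BP1, 383312 in shIGF2BP2 and 376999 in shIGF2BP3. Single libraries are not in this table, so the depth per library and the spread between the 3 untreated libraries are unknown. No p-value across genes is given for expression, apart from a permutation of genes between chromosomes, which does not measure that spread. The deposited half-life tables, 1 per replicate, hold 10079 genes for shNS, shIGF2BP1 and shIGF2BP3. The authors computed each RNA half-life from expression at 1, 3 and 6 h of actinomycin D relative to untreated cells, with 2 biological replicates per line, per the series' design text. The header names no unit of time, and hours were taken from the time points. Whether the authors scaled the values to the ERCC transcripts is not given in the sources used here. ERCC transcripts were also written down as a list, and their values were not used here. The authors' log2 quotients, 2 columns per half-life table, were not used, because a quotient of 2 negative half-lives is positive.

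A half-life is negative where the fitted RNA level rose after the drug. If levels were scaled to mapped reads, a stable mRNA gains share as others decay, and rates and hours are relative to the pool. In shNS 29.9% of the genes with a value in replicate 1 and 24.2% in replicate 2 were negative. The shares were 12.0% and 14.8% in shIGF2BP1, and 16.2% and 5.01% in shIGF2BP3. The test on log2 half-life therefore covers the 5443 genes with a positive half-life in all 6 columns, 54.0% of each table. The decay rate, ln 2 divided by the half-life, keeps negative values and is defined in all 6 columns for 10017 genes. It served for descriptions of all genes and as an alternative to the log2 half-life.

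Expression was compared as the difference of log2(average RPKM + 1) between each knockdown line and shNS. Genes were counted as higher or lower at a difference of at least 1, a 2-fold change, among the 12893 genes with a mean of at least 1 RPKM over the 4 averages. The median difference of each gene list was placed as a percentile among 10000 random lists of the same size drawn from the same 20 bins of mean expression. Percentiles below 2.5 or above 97.5 are called outside the central 95% of random lists. Lists needed at least 5 measured members. In data simulated from the shIGF2BP1 comparison, 3 of 40 lists of 30 genes without a shift fell outside that range, as did 23 with a shift of 0.25 and 40 with a shift of 0.5. The likeness of the 3 knockdown lines was measured by Spearman correlation across genes, beside values simulated for unchanged lines that share 1 control.

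Half-lives were compared with limma 3.58.1 in R 4.3.3 on log2 half-life, with all 6 columns in 1 fit, the replicate table as a block and an empirical Bayes prior that follows a trend on the mean. The fit had 2 residual and 3.11 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg's method over the 5443 genes, and a gene was called at an adjusted p under 0.05. These p-values measure the spread between the 2 biological replicates. Tested on simulated data of the same size, the shIGF2BP3 comparison called 29 of 50 genes given a log2 change of -2, 2 of 50 at -1, 2 of 50 at 1, 16 of 50 at 2, and 10 of 5243 unchanged genes. The simulated noise was independent between genes, while real columns also move as a whole, so these shares may not carry over to the data. With 2 columns against 2, an exact permutation test on column medians cannot give a p below 0.333. Gene lists were tested with camera of limma, which compares a list with all other genes, at a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry, which tests whether a list's genes move on balance in 1 direction. Camera compares changes divided by their standard error (SE), so a called list need not have a larger change than other genes. With an estimated correlation, camera takes its p-value from the 2 residual degrees of freedom, so it could call few lists. A call lost in that run does not show that correlation between genes explains the call. In the half-life results of a list, a count adjusted over the list alone corrects only for the members of that list.

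Whether equal replicate numbers mark samples handled together was checked on the half-life deviations of each column from its line's mean. The Spearman correlation across genes was 0.06 between shNS and shIGF2BP1, -0.06 between shNS and shIGF2BP3 and -0.39 between shIGF2BP1 and shIGF2BP3, so the numbers do not pair the samples. The block was kept because it was part of the design, and the fit without it is given as an alternative.

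The comparisons, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists were the IGF2BP family, 4 genes that the study itself put forward as targets (MYC, FSCN1, TK1 and MARCKSL1), IGF2BP targets from the literature, S phase, mitosis, MYC-activated ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, secreted hepatocyte proteins, liver metabolism, cholesterol synthesis, glycolysis, immediate early genes, AU-rich cytokines and growth factors, the interferon response, p53 targets, the unfolded protein and amino acid stress response, the m6A machinery, the mRNA decay machinery, the actin cytoskeleton and adhesion, C2H2 zinc finger genes, replication-dependent histones, mitochondrially encoded genes, markers of other cell types and reference genes. The IGF2BP family and the 4 study targets are always named. For expression, the named genes are the 10 highest and the 10 lowest of each line. For half-life, they are the 10 most shortened and the 10 most prolonged called genes with the same sign in both replicates and at least 1 RPKM in shNS, or, where fewer than 5 genes were called in a direction, genes from the 10 with the smallest p, as values only. Up to 4 members with the largest difference are named per list. CDA, DPP4, MCM10, TUBB and AFP, TOP2A expression in shIGF2BP2, CCNB1 expression in shIGF2BP3 and the half-lives of TBRG4, TSR1 and DTX3L in shIGF2BP3 lie outside that rule and were chosen after their values were seen. Symbols of clones, pseudogenes and small RNAs were left out of the named genes, and some genes that the rule names are not reported here.

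Alternatives for expression were a pseudocount of 0.1 RPKM, no filter, a filter at 5 RPKM, a 1.5-fold difference and columns centred on their median. Alternatives for half-life were a ceiling of 24 h, genes with a mean half-life under 12 h, genes with a mean of at least 1 RPKM, no replicate block, centred columns, the decay rate, a robust prior and leaving out each column in turn. GC content and length were taken from the reference annotation by gene symbol. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.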

Results

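HepG2 lines with a stable hairpin against 1 of the 3 IGF2BP proteins, RNA-binding proteins that bind and stabilise target mRNAs and read N6-methyladenosine (m6A), were compared with a line carrying a control hairpin (shNS). RNA was sequenced from untreated cells of all 4 lines, in triplicate, and from shNS, shIGF2BP1 and shIGF2BP3 cells after 1, 3 and 6 h of actinomycin D, in duplicate. Of the 30 libraries, shNS, shIGF2BP1 and shIGF2BP3 have 9 each and shIGF2BP2 has 3. Expression is given as the authors' average RPKM per line, without a replicate spread, and the depth per library is unknown. Half-lives are given in hours as the mean ± SD of 2 replicates. Log2 differences and log2 changes are knockdown minus shNS throughout.

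The first comparison asks how far each hairpin lowered its target and where the genes that the study put forward as IGF2BP targets stood. IGF2BP1 averaged 78.1 RPKM in shNS and 17.1 RPKM in shIGF2BP1, a log2 difference of -2.13. IGF2BP2 was 38.4 RPKM in shNS and 13.7 RPKM in shIGF2BP2 (-1.42). IGF2BP3, the least expressed of the family in shNS, was 6.94 RPKM there and 3.65 RPKM in shIGF2BP3 (-0.77, or -0.47 with columns centred on their medians), less than a 2-fold difference. At this low level the added 1 RPKM makes the log2 difference smaller than the averages alone would give. The other family members also differed between the lines. IGF2BP1 was lower in shIGF2BP2 (45.7 RPKM, -0.76) and in shIGF2BP3 (42.7 RPKM, -0.85, or -0.55 when centred). IGF2BP3 was higher in shIGF2BP1 (26.5 RPKM, 1.79) and in shIGF2BP2 (12.3 RPKM, 0.75), and IGF2BP2 was at 37.8 RPKM in shIGF2BP1 and 41.5 RPKM in shIGF2BP3.

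FSCN1, which encodes the actin-bundling protein fascin, TK1, a thymidine kinase of S phase, and MARCKSL1, an actin-regulating membrane protein, were lower in all 3 lines. FSCN1 was 76.4 RPKM in shNS, 31.1 RPKM in shIGF2BP1, 32.4 RPKM in shIGF2BP2 and 6.01 RPKM in shIGF2BP3. TK1 was 28.1 RPKM in shNS and 6.19, 2.61 and 5.88 RPKM in the same lines. MARCKSL1 was 215 RPKM in shNS and 108, 47.8 and 71.1 RPKM in the same lines, with a log2 difference of -0.99 in shIGF2BP1. MYC, the transcription factor of growth and ribosome production, was 76.9 RPKM in shNS, 34.6 RPKM in shIGF2BP1 (-1.13), 83.3 RPKM in shIGF2BP2 (0.11) and 38.6 RPKM in shIGF2BP3 (-0.98). The study put these 4 genes forward as targets and may have drawn on these same samples, so they are not taken as independent evidence of a direction.

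**Figure D1:**
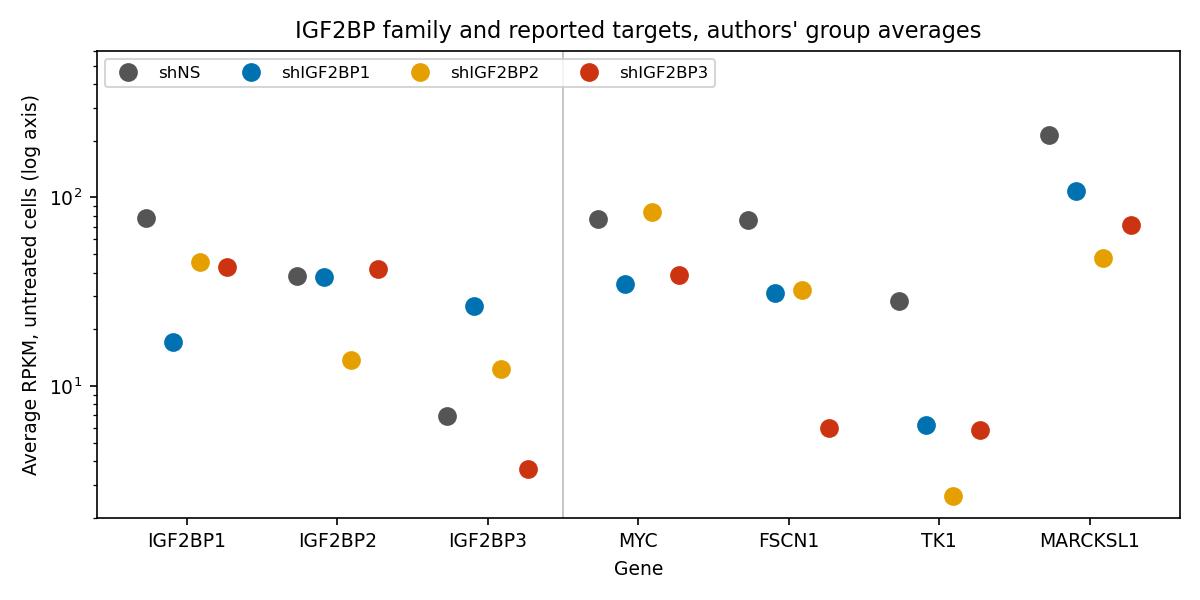
Average RPKM in untreated cells (log axis) of the 3 IGF2BP genes and the 4 study targets, with 1 point per line standing for the authors' average. Each hairpin's target is lower in its own line, by a difference of log2(average RPKM + 1) of -2.13 for IGF2BP1, -1.42 for IGF2BP2 and -0.77 for IGF2BP3 (-0.47 when centred).

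The next comparisons ask which genes differed between each knockdown line and shNS in untreated cells. Whether the lowered target, another effect of the hairpin or the selection of the line led to a difference was not tested. In shIGF2BP1, genes of the interferon response were higher, and genes of S phase, mitosis and ribosome biogenesis were lower. IFI27 was 0.36 RPKM in shNS and 26.6 RPKM in shIGF2BP1, IFI6 was 6.99 and 129 RPKM, and IFIT1, a sensor of foreign RNA, was 0.23 and 13.0 RPKM. GSTA1 and GSTA2, glutathione transferases of the hepatocyte, were 2.23 and 0.78 RPKM in shNS and 44.0 and 17.6 RPKM in shIGF2BP1. SYT11, DUOX2, TMEM27, PLPPR1 and PLXNC1 were also among the 10 highest, with log2 differences from 2.75 for PLXNC1 to 3.54 for SYT11. Lower were the chemokine CXCL8 (14.1 RPKM in shNS and 0.37 RPKM in shIGF2BP1), the matrix protease MMP2 (10.3 and 0.35 RPKM), the matrix proteoglycan VCAN (13.5 and 0.99 RPKM), the cytokine IL11 (23.4 and 2.37 RPKM) and cyclin D2 (CCND2, 7 and 0.14 RPKM). AKAP12, a scaffold of kinase signalling, was 84.0 RPKM in shNS and 9.96 RPKM in shIGF2BP1, and HPD, an enzyme of tyrosine breakdown, was 201 and 34.1 RPKM. In all, 652 genes were higher and 551 lower by 2-fold or more, a balance that turned to 568 and 633 with the columns centred on their medians.

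By gene list, S phase genes in shIGF2BP1 had a median log2 difference of -0.90, with 19 of 44 lower by 2-fold or more, for example the replicative helicase subunit MCM5 (13.9 RPKM in shNS and 4.02 RPKM in shIGF2BP1). Mitosis genes had a median of -1.0, with 21 of 41 lower, for example cyclin B1 (CCNB1, 35.7 and 11.7 RPKM). MYC-activated ribosome biogenesis genes had a median of -0.70, with 6 of 38 lower, among them MYBBP1A (32.6 and 11.7 RPKM) and the nucleolar helicase DDX21 (127 and 57.0 RPKM). Cytosolic ribosomal proteins had a median of -0.67 with 4 of 73 lower, for example RPS12 (784 and 306 RPKM), although their reads are hard to tell from those of pseudogenes. All 4 of these lists were at percentile 0 of the random lists, as were AU-rich cytokines and growth factors (-1.11, 6 of 12 lower), which include TNFAIP3, an inhibitor of NF-kappaB signalling (26.6 and 5.19 RPKM). The interferon response was higher, with a median of 0.96 at percentile 100 and 13 of 26 genes higher, for example the antiviral GTPase MX1 (2.16 and 15.7 RPKM). Secreted hepatocyte proteins had a median of 0.26 at percentile 100 but moved both ways. FGB, a chain of fibrinogen, was 164 RPKM in shNS and 1031 RPKM in shIGF2BP1, while APOA2, an apolipoprotein of high-density lipoprotein, was 369 and 112 RPKM. Literature IGF2BP targets had a median of -0.61 at percentile 0.01, with 7 of 24 lower, among them the chromatin protein HMGA1 (160 and 43.6 RPKM), cyclin D1 (CCND1, 155 and 52.8 RPKM) and the microtubule regulator STMN1 (60.5 and 16.3 RPKM). Also outside the central 95% of random lists were p53 targets (-0.36, percentile 0.58), actin and adhesion genes (-0.42, percentile 0.15) and C2H2 zinc finger genes (0.24, percentile 100). No member of the markers of other cell types was higher by 2-fold or more, and the list's median was -0.34.

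In shIGF2BP2, S phase, mitosis and hepatocyte genes were lower, and immediate early genes were higher. The kinase of mitotic entry CDK1 was 25.6 RPKM in shNS and 1.12 RPKM in shIGF2BP2, the transcription factor MYBL2 was 42.1 and 2.31 RPKM, cyclin A2 (CCNA2) was 21.0 and 1.23 RPKM and the ubiquitin-conjugating enzyme UBE2C was 31.3 and 2.62 RPKM. FGA, another fibrinogen chain, was 266 and 18.4 RPKM, isocitrate dehydrogenase IDH1 was 178 and 15.3 RPKM and the citrate carrier SLC25A1 was 94.3 and 8.30 RPKM. RPL13A (277 and 28.8 RPKM) and RPL27A (53.8 and 4.67 RPKM) were also among the 10 lowest. The highest were the carboxypeptidase CPA4 (2.76 and 226 RPKM), the phospholipid-binding protein ANXA1 (0.47 and 85.4 RPKM), the keratin-associated KRTAP3-1 (36.0 and 2085 RPKM) and the noncoding RNA UCA1 (0.32 and 57.8 RPKM). They were followed by collagen COL1A1 (0.58 and 30.1 RPKM), the protease-activated receptor F2RL1 (23.6 and 455 RPKM), SP140 (0.64 and 29.1 RPKM), the apoptosis inhibitor BIRC7 (2.25 and 55.8 RPKM), FLG-AS1 (0.79 and 28.7 RPKM) and the growth factor binding protein IGFBP3 (2.47 and 56.2 RPKM). In this line 935 genes were higher and 1249 lower by 2-fold or more, the most of the 3 lines with these settings. More genes were lower in shIGF2BP3 than in shIGF2BP2 at a 1.5-fold difference (3489 and 2674) and with a pseudocount of 0.1 RPKM (1690 and 1669).

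Among the lists in shIGF2BP2, mitosis genes were the lowest, with a median of -2.38 and 39 of 41 lower by 2-fold or more, for example topoisomerase TOP2A (55.3 RPKM in shNS and 5.54 RPKM in shIGF2BP2). S phase genes had a median of -1.51 with 32 of 44 lower, for example the ribonucleotide reductase subunit RRM2 (31.6 and 2.74 RPKM). Ribosome biogenesis genes (-0.58, 11 of 38 lower) and cytosolic ribosomal proteins (-0.84, 30 of 73 lower) were lower as well, at percentiles 0.05 and 0. Secreted hepatocyte proteins had a median of -0.76 at percentile 0 with 18 of 42 lower, for example haptoglobin (HP, 43.2 and 4.95 RPKM), and liver metabolism genes a median of -0.36 at percentile 1.81 with 12 of 38 lower, for example the bile acid enzyme CYP27A1 (62.9 and 9.50 RPKM). Immediate early genes were higher, with a median of 1.08 and 18 of 34 higher, for example the transcription factor EGR1 (14.4 and 205 RPKM) and the phosphatase DUSP5 (7.97 and 78.8 RPKM). AU-rich cytokines and growth factors (0.88, 5 of 12 higher), among them the cytokine LIF (5.12 and 35.4 RPKM), and p53 targets (0.57, 7 of 28 higher), among them the ribonucleotide reductase subunit RRM2B (15.4 and 66.5 RPKM), were at percentile 100 like the immediate early genes. Markers of other cell types had a median of 0.55 at percentile 97.2, with 3 of 6 higher and 1 lower by 2-fold or more. COL1A1, PDGFRB (1.31 and 8.90 RPKM) and smooth muscle actin ACTA2 (20.9 and 69.4 RPKM) were higher, and lysozyme (LYZ, 531 and 121 RPKM) was lower.

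In shIGF2BP3, hepatocyte genes were higher and genes of the cytoskeleton lower. G6PC, the glucose-6-phosphatase of gluconeogenesis, was 0.52 RPKM in shNS and 45.5 RPKM in shIGF2BP3, kininogen (KNG1) was 2.07 and 82.7 RPKM, GSTA1 was 2.23 and 81.4 RPKM and the deiodinase DIO1 was 4.48 and 92.8 RPKM. The fatty acid carrier FABP1 was 32.0 and 522 RPKM, APOA4 was 1.60 and 38.5 RPKM, ITIH1 was 0.85 and 25.6 RPKM and the death ligand TNFSF10 was 0.98 and 28.5 RPKM. ALDH8A1 and ACSM2A, at 0.75 and 0.64 RPKM in shNS and 25.9 and 20.4 RPKM in shIGF2BP3, completed the 10 highest. Albumin (ALB) was 2787 RPKM in shNS and 32512 RPKM in shIGF2BP3, against 9543 RPKM in shIGF2BP1 and 3723 RPKM in shIGF2BP2. Among the lowest were the tubulins TUBA1A (74.4 and 2.75 RPKM) and TUBB2B (30.2 and 2.37 RPKM), the matrix protein MATN3 (280.2 and 13.5 RPKM), the sulfatase ARSI (32.4 and 0.65 RPKM), the biliary and progenitor keratin KRT19 (739 and 74.3 RPKM) and FSCN1. KRTAP3-1 (36.0 and 2.51 RPKM), IL11 (23.4 and 1.08 RPKM) and CXCL8 (14.1 and 0.53 RPKM) were also among the 10 lowest. The median of all genes in this line was -0.30, and 517 genes were higher and 1001 lower by 2-fold or more. With the columns centred on their medians the balance turned, to 861 higher and 414 lower.

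Relative to that median of -0.30, secreted hepatocyte proteins in shIGF2BP3 had a centred median of 1.90 with 36 of 42 higher by 2-fold or more (1.60 and 32 as deposited), cholesterol synthesis genes 1.48 with 17 of 24 higher (1.17 and 16) and liver metabolism genes 0.96 with 19 of 38 higher (0.66 and 16), all at percentile 100 and with 0 members lower by 2-fold. Examples were FETUB (1.06 RPKM in shNS and 22.1 RPKM in shIGF2BP3), the sterol oxidase MSMO1 (60.1 and 186 RPKM), the glucose transporter SLC2A2 (3.15 and 25.8 RPKM) and the urea cycle enzyme ARG1 (0.14 and 7.96 RPKM). Actin and adhesion genes had a centred median of -0.89 with 18 of 40 lower by 2-fold or more (-1.19 and 26 as deposited), S phase genes -0.77 with 13 of 44 lower (-1.07 and 25), mitosis genes -0.51 with 7 of 41 lower (-0.81 and 13) and ribosome biogenesis genes -0.56 with 5 of 38 lower (-0.86 and 12), all at percentile 0. TAGLN, an actin-binding protein, was 19.3 and 3.37 RPKM, while E-cadherin (CDH1) went the other way, at 7.44 and 63.5 RPKM. AU-rich cytokines and growth factors (-0.62 centred, percentile 0.01), literature IGF2BP targets (-0.44, percentile 0.08) and glycolysis genes (-0.31, percentile 1.47) were also below the central 95% of random lists. In the last list, the glucose transporter SLC2A1 was 230 RPKM in shNS and 38.7 RPKM in shIGF2BP3. The interferon response was above it (0.33 centred, percentile 99.5), with 4 of 26 genes higher and 3 lower as deposited. Cytosolic ribosomal proteins were at percentile 98.3, with a median of -0.24 as deposited that turned to 0.06 when centred, and they were within the central 95% (percentile 96) once a trend on GC content and length was removed. Markers of other cell types had a median of -0.21 as deposited and 0.09 when centred, within the central 95%.

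Several lists were within the central 95% of random lists in every line, in the order shIGF2BP1, shIGF2BP2 and shIGF2BP3 as deposited. Medians were -0.03, -0.26 and -0.26 for nuclear-encoded oxidative phosphorylation, -0.29, -0.30 and -0.23 for unfolded protein and amino acid stress, -0.01, -0.10 and -0.40 for the m6A machinery, and 0.07, 0.03 and -0.38 for the mRNA decay machinery. They were 0.32, -0.05 and -0.19 for histones, -0.20, 0.17 and -0.30 for mitochondrially encoded genes and -0.17, 0.06 and -0.47 for reference genes. Single members still stood out. In shIGF2BP2, ASNS and PHGDH, enzymes of amino acid synthesis, were at 9.84 and 7.07 RPKM against 75.1 and 45.2 RPKM in shNS, and the poly(A)-binding protein PABPC1 was at 110.2 RPKM against 345 RPKM. The decapping enzyme DCP2 was 6.11 RPKM in shNS and 33.5 RPKM in shIGF2BP1.

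**Figure D2:**
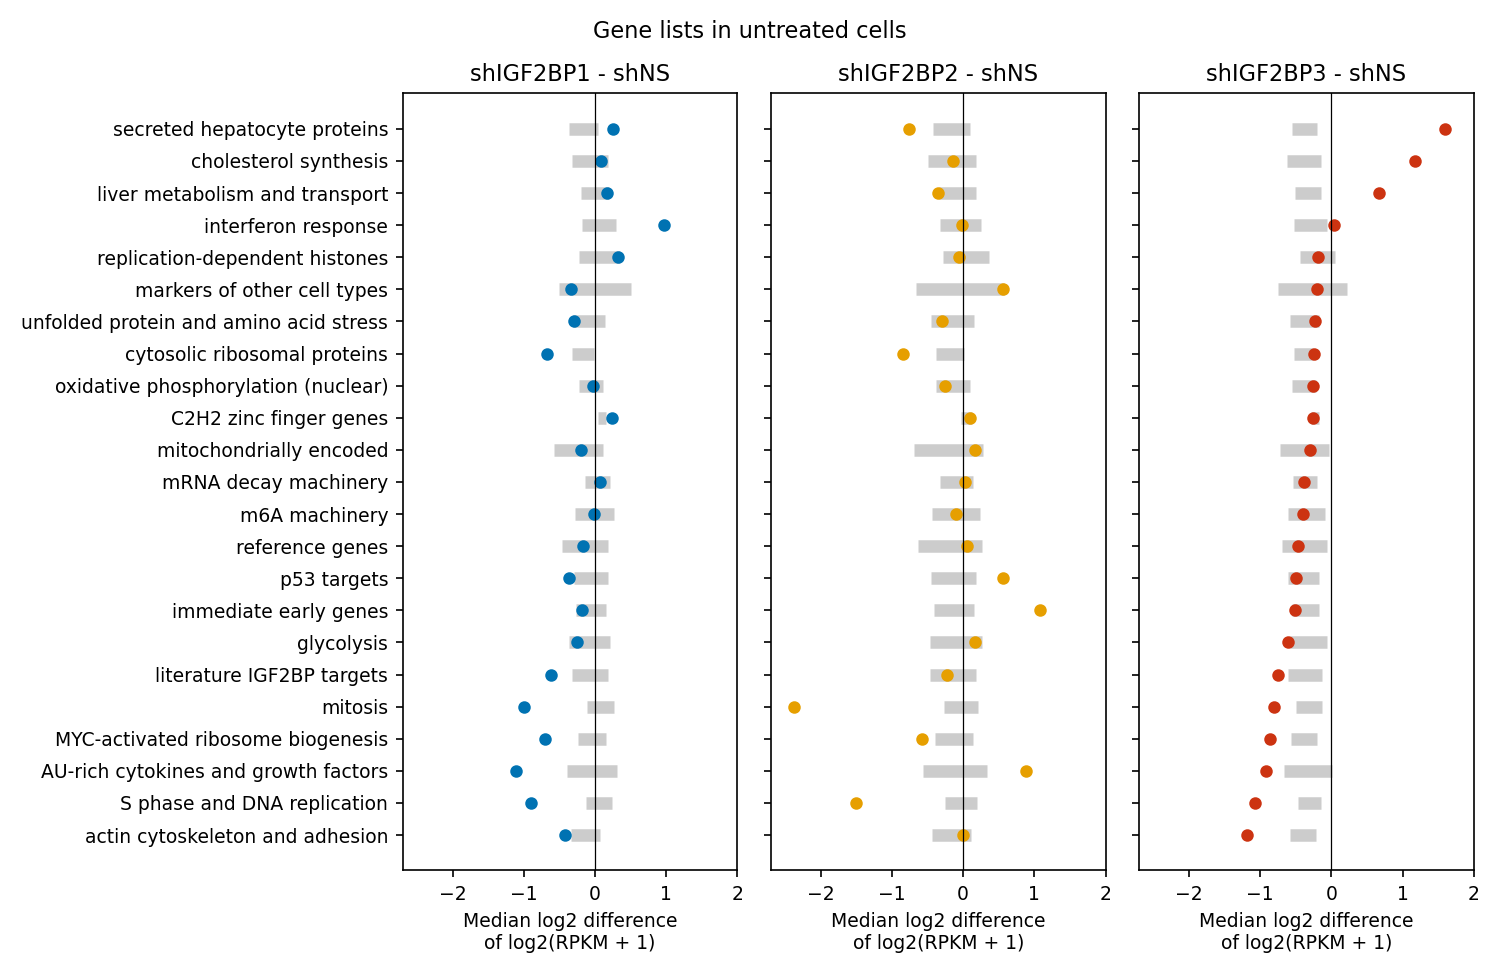
Median log2 difference of log2(RPKM + 1) against shNS for each gene list in untreated cells, with 1 panel per knockdown line, points for the lists and grey bars for the central 95% of 10000 expression-matched random lists. Mitosis genes are lower in every panel (-1.0, -2.38 and -0.81), and secreted hepatocyte proteins are higher in shIGF2BP1 (0.26) and shIGF2BP3 (1.60) and lower in shIGF2BP2 (-0.76).

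The 3 lines were then compared with each other. In every line, 99 genes were lower by 2-fold or more and 24 were higher, where unchanged lines that share 1 control would give 84 and 65 in a simulation. With columns centred on their medians the counts were 52 and 33, and 60 and 72 in the simulation, so the number of shared lower genes exceeded the simulated one as deposited but not when centred. The 99 genes hold 14 of the S phase list (8 when centred), among them TK1, MCM5 and MCM10, and 10 of the mitosis list (5 when centred), among them CDK1 and TOP2A. They also hold HMGA1, STMN1, FSCN1, the tubulin TUBB and TAGLN. The 24 higher genes include SLC2A2, the cytidine deaminase CDA and the peptidase DPP4. Across genes, which are not independent replicates, the Spearman correlation of the log2 differences was 0.31 between shIGF2BP1 and shIGF2BP2, 0.46 between shIGF2BP1 and shIGF2BP3 and 0.18 between shIGF2BP2 and shIGF2BP3. The shared control alone gave 0.47 to 0.48 in simulated unchanged lines, so none of the 3 correlations exceeded it. These simulations rest on a single draw each, so the spread of the simulated values is not known. They also give shNS and every line noise of equal size, and averages do not show how much of the differences is noise. They therefore do not tell whether the likeness of the lines goes beyond the shared control. Genes lower in both lines of a pair numbered 212, 262 and 213 in the same order, against 210, 186 and 363 in the simulation. Genes higher in both numbered 131, 134 and 57, against 200, 142 and 167. As deposited, shIGF2BP1 and shIGF2BP3 thus shared more lower genes than the single simulated draw gave, while no pair shared more higher genes. Genes that were higher in 1 line and lower in the other numbered 97, 25 and 210 for the same pairs. Hepatocyte lists parted in the last pair, with FGA, HP and CYP27A1 lower in shIGF2BP2 and G6PC, KNG1 and ALB higher in shIGF2BP3.

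Half-lives in shNS describe mRNA stability before the knockdown comparisons. Immediate early genes were the fastest list, with a half-life from the median decay rate of 1.03 h in replicate 1 and 1.01 h in replicate 2, against 12.3 and 9.43 h for all genes. C2H2 zinc finger genes (3.36 and 2.92 h), mitochondrially encoded genes (5.64 and 2.86 h), the m6A machinery (4.53 and 3.07 h), p53 targets (4.55 and 3.98 h), AU-rich cytokines and growth factors (3.84 and 3.36 h), the mRNA decay machinery (5.26 and 5.38 h) and ribosome biogenesis genes (7.41 and 4.78 h) also decayed faster than the central 95% of random lists. At the slow end, mRNAs of cytosolic ribosomal proteins had negative median rates of -0.0412 and -0.0521 per h, secreted hepatocyte proteins -0.0284 and -0.0517 per h, histones -0.0276 and -0.0114 per h and oxidative phosphorylation genes -0.0181 and -0.0138 per h. All 4 were slower than the central 95% of random lists, although histones were inside it, at percentile 2.55, without shNS replicate 2. A negative rate means that the measured level rose after the drug, which a stable mRNA would also show on a scale relative to mapped reads. These values therefore give an order and no half-life.

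**Figure D3:**
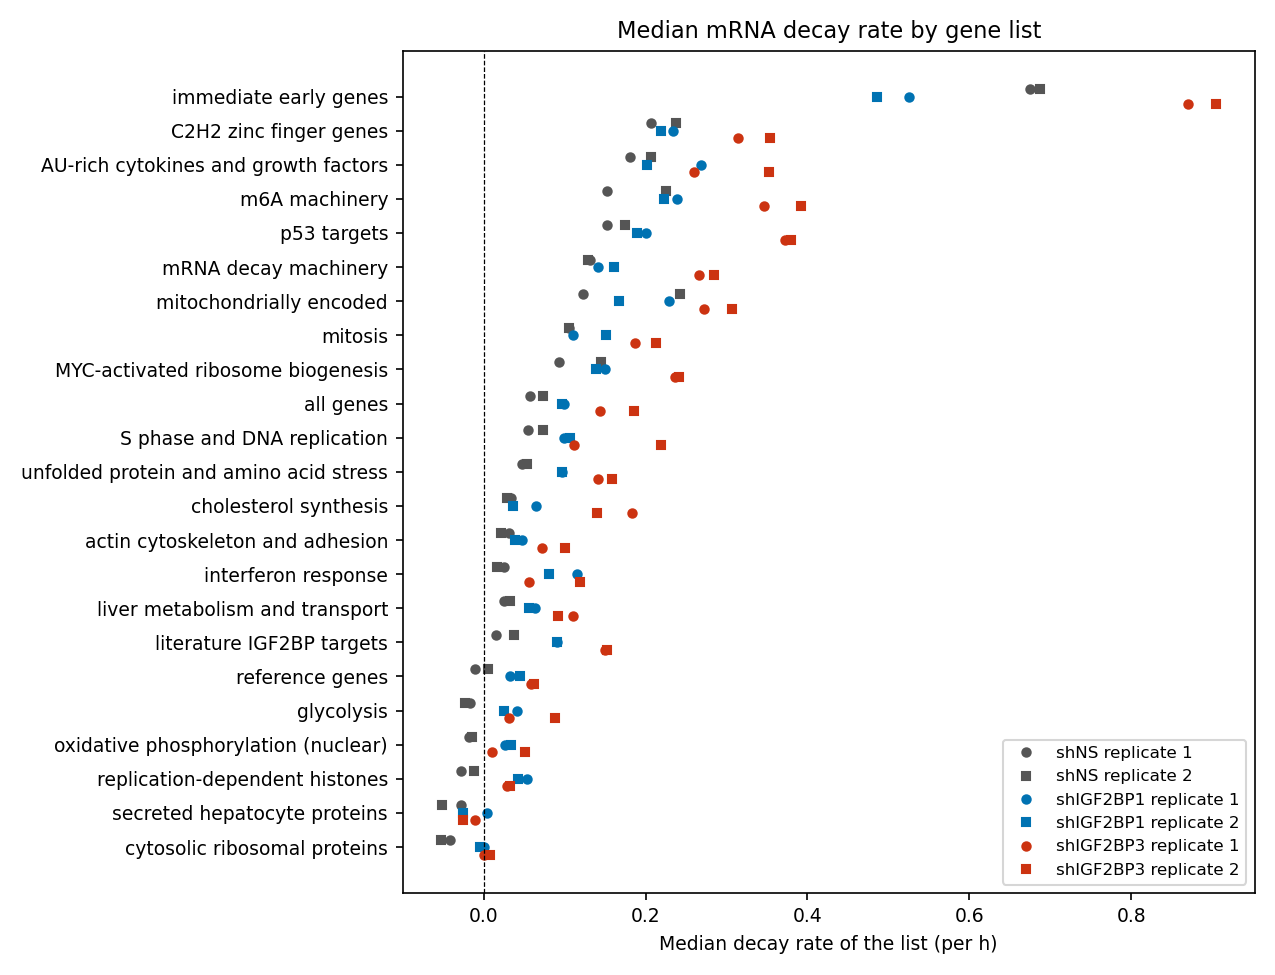
Median decay rate per h of each gene list, with 1 point for each of the 2 replicates of shNS, shIGF2BP1 and shIGF2BP3. Immediate early genes are fastest in shNS, at half-lives of 1.03 and 1.01 h, and ribosomal protein mRNAs slowest, at rates of -0.0412 and -0.0521 per h.

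The central comparison asks whether mRNAs were shorter-lived in shIGF2BP1 than in shNS. Single mRNAs with the smallest p went both ways. XBP1, the transcription factor of the unfolded protein response, had a half-life of 1.53 ± 0.0881 h in shNS and 0.816 ± 0.0544 h in shIGF2BP1 (log2 change -0.91, SE 0.08). SESN2, a stress-induced regulator of growth signalling, was at 2.06 ± 0.125 and 1.10 ± 0.0557 h, and the mitochondrial ribosomal protein MRPL44 at 4.80 ± 0.395 and 1.60 ± 0.155 h. GORASP2, a Golgi stacking protein, RAE1, an mRNA export factor, and RBM15B, an m6A cofactor, had log2 changes of -1.52, -1.27 and -1.56. On the other side, NFKBIA, the inhibitor of NF-kappaB, was at 0.548 ± 0.01 h in shNS and 0.908 ± 0.0226 h in shIGF2BP1 (0.73, SE 0.06). The transcription factor SOX9 was at 0.689 ± 0.0197 and 1.09 ± 0.0804 h, and PA2G4, a factor of ribosome production, at 2.36 ± 0.291 and 24.4 ± 2.71 h. None of these passed the test, with a smallest adjusted p of 0.148 by limma. By limma 0 of 5443 genes were called shortened and 0 prolonged, and 945 had an unadjusted p under 0.05, while without the replicate block 17 were called shortened and 12 prolonged. With columns centred on their medians, 16 were called shortened and 55 prolonged relative to the median gene. The median log2 change was -0.28 in replicate 1 and -0.07 in replicate 2, with 64.7% and 54.1% of genes shorter-lived, and the column medians differed by -0.20 (exact permutation p = 0.333, the smallest possible).

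Of the study targets, MYC mRNA was at 0.719 ± 0.0004 h in shNS and 0.950 ± 0.023 h in shIGF2BP1 (0.40, SE 0.07, limma adjusted p = 0.183). FSCN1 was at 1.69 and 44.1 h in the 2 shNS replicates and 4.37 and 13.7 h in shIGF2BP1 (-0.15, limma adjusted p = 0.965). TK1 (11.1 and -43.7 h in shNS) and MARCKSL1 (-7.42 and 18.8 h) had a negative value in shNS and were not tested, and neither was IGF2BP3 (-6.63 and 8.10 h). IGF2BP1 mRNA itself was at 6.20 ± 1.4 h in shNS and 3.12 h in shIGF2BP1 (-0.97, limma adjusted p = 0.238), and IGF2BP2 mRNA was at 20 ± 16 and 443 h.

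Relative to the other genes, 4 lists differed in shIGF2BP1 by camera of limma at the preset correlation. With an estimated correlation none of the 4 was called (camera adjusted p = 0.851 for each), in a run on 2 residual degrees of freedom that could call little. S phase genes (12 tested) had a median change of -0.95 against -0.18 for all genes (adjusted p = 0.0440), oxidative phosphorylation genes (6 tested) -1.64 (adjusted p = 0.0440) and interferon genes (8 tested) -0.78 (adjusted p = 0.0440). Examples were FEN1, a nuclease of DNA replication (8.21 h in shNS and 2.60 h in shIGF2BP1), NDUFA9, a subunit of complex I (63.0 ± 9.6 and 3.82 h), and DTX3L, a ubiquitin ligase (2.98 and 1.68 h). Immediate early genes (14 tested) went the other way, with a median of 0.34 but a mean of -0.0032 (adjusted p = 8.06e-06), for example IER2 (1.83 and 3.26 h) and ID2 (0.868 and 1.42 h). Adjusted over the list alone, 4 S phase genes, 1 oxidative phosphorylation gene, 2 interferon genes and 1 immediate early gene were shortened and 9 immediate early genes prolonged, against 0 in each list when adjusted over all genes. Leaving out 1 column at a time gave adjusted p from 0.0402 to 0.184 for S phase, 0.0478 to 0.213 for oxidative phosphorylation, 0.0583 to 0.160 for interferon and 4.46e-11 to 0.0254 for immediate early genes. Literature IGF2BP targets had a median change of -1.11 over 12 genes without passing (adjusted p = 0.172), with 0 shortened and 1 prolonged when adjusted over the list alone and 0 over all genes. Among its members, SRF was at 118 ± 160 h in shNS and 2.71 h in shIGF2BP1, and beta-catenin (CTNNB1) at 25.5 and 8.85 h. The other lists had medians from -0.49 for unfolded protein and amino acid stress to 0.41 for AU-rich cytokines and growth factors, a list whose mean was -0.14.

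In shIGF2BP3, mRNAs were shorter-lived across most of the genes tested, and by limma the half-lives of 456 genes fell and those of 4 rose among 5443, with 2545 at an unadjusted p under 0.05. A uniform shift of every gene by the median change of -0.86 gave 1956 calls in simulated data, against 460 observed. That simulation draws noise for each gene separately, without the movement of whole columns in the data, so its count does not carry over. With columns centred on their medians 13 genes were called shortened, so most calls do not set genes apart from a shift of all genes. The most shortened included CPOX, an enzyme of heme synthesis (46.9 ± 4.25 h in shNS and 1.85 ± 0.244 h in shIGF2BP3, log2 change -4.67, SE 0.60), MMS19, a factor of iron-sulfur cluster assembly (196 ± 146 and 2.55 ± 0.514 h, -6.04, SE 0.83), the receptor phosphatase PTPRG (244 ± 200.4 and 3.95 ± 0.154 h, -5.65, SE 1.08) and CACFD1 (25.2 ± 3.11 and 1.22 ± 1.28 h, -4.92, SE 0.75). NDST1, an enzyme of heparan sulfate synthesis, fell from 133 ± 23.9 to 6.03 ± 3.00 h, ZFAND6 from 39.4 ± 17.1 to 1.89 ± 0.0423 h, the nuclear import factor KPNA6 from 54.7 ± 4.64 to 2.99 ± 0.407 h and the antiviral protease FAM111A from 62.2 ± 47.4 to 3.03 ± 0.113 h. The mitochondrial mutase MUT, at 59.0 ± 14.3 and 3.53 ± 0.257 h, and MPI, a mannose phosphate isomerase, at 33.8 ± 21.2 and 1.97 ± 0.646 h, completed the 10 (limma adjusted p = 0.0498 for each). Half-lives far beyond the 6 h of the time course are extrapolated. The prolonged mRNAs were PLEKHM2, a lysosome transport factor (0.988 ± 0.164 and 4.57 ± 1.41 h, log2 change 2.18), MRTO4, a factor of ribosome assembly (1.56 ± 0.769 and 4.65 ± 1.43 h, 1.63), TP53INP2, a regulator of autophagy (2.23 ± 0.0632 and 5.68 ± 0.518 h, 1.34), and NFKBIA (0.548 ± 0.01 and 0.676 ± 0.0159 h, 0.30). These 4 calls were lost with the decay rate in place of log2 half-life and when any 1 column was left out. In simulated data with noise drawn for each gene separately, 10 of 5243 unchanged genes were called, a share that may not carry over to the data.

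Over all tested genes the median log2 change in shIGF2BP3 was -0.86 in replicate 1 and -0.83 in replicate 2, with 84.1% and 91.6% of genes shorter-lived. The median half-life was 5.72 and 4.90 h in shNS, 4.53 and 4.68 h in shIGF2BP1, and 3.01 and 2.64 h in shIGF2BP3. Column medians in shIGF2BP3 and shNS differed by -0.91 (exact permutation p = 0.333, the smallest that 2 against 2 can give). The called genes had adjusted p from 0.0498 to 0.0499, close to the threshold. A fit without 1 column has fewer residual degrees of freedom, so calls this near the threshold are easily lost there. Without either column of shIGF2BP1, for example, the median change in shIGF2BP3 stayed at -0.86. The shortened calls went to 0 when shNS replicate 1 or any 1 column of shIGF2BP1 or shIGF2BP3 was left out (with 1 prolonged gene called without shNS replicate 1), and with the decay rate in place of log2 half-life, while 515 shortened and 57 prolonged were called without shNS replicate 2. Without the replicate block 1775 genes were called shortened and 16 prolonged, and with columns centred on their medians 13 genes were called shortened and 274 prolonged relative to the median gene.

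**Figure D4:**
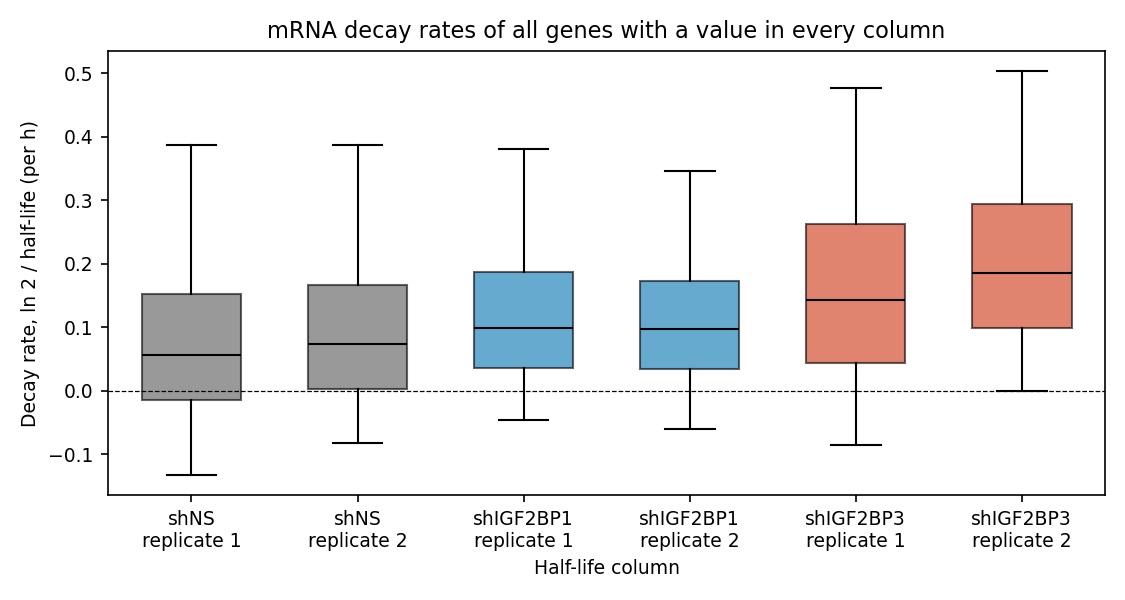
Decay rate per h of the 10017 genes with a value in all 6 half-life columns, as boxes from the lower to the upper quartile with a line at the median and whiskers at the 5th and 95th percentiles. Medians are 0.0569 and 0.0739 per h in shNS, 0.0990 and 0.0974 per h in shIGF2BP1, and 0.144 and 0.185 per h in shIGF2BP3.

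Members of most lists were shortened along with the other genes in shIGF2BP3. Adjusted over the list alone, 10 of 12 literature IGF2BP targets were shortened and 2 when adjusted over all genes, among them BTRC, a subunit of a ubiquitin ligase (7.70 h in shNS and 1.60 h in shIGF2BP3). The same 2 counts were 6 and 1 of 12 S phase genes, with the histone mRNA binding protein SLBP at 8.59 ± 1.5 and 2.12 h, and 3 and 1 of 9 mitosis genes, with CCNB1 at 6.39 ± 1.4 and 2.28 h. They were 11 and 4 of 27 ribosome biogenesis genes, with TBRG4 (7.74 and 2.38 h) and TSR1 (8.25 and 2.80 h), and 4 and 3 of 8 interferon genes, with DTX3L at 2.98 and 1.45 h. Among p53 targets they were 10 and 6 of 22, with SESN1 at 4.87 ± 0.23 and 1.27 h, and among stress response genes 8 and 4 of 14, with HERPUD1, a factor of protein quality control, at 4.93 and 1.75 h. For the m6A machinery they were 10 and 3 of 18, with the demethylase FTO at 21.4 ± 5.0 and 2.60 h, and for the mRNA decay machinery 8 and 4 of 38, with the Argonaute protein AGO1 at 15.0 ± 3.9 and 2.60 h. Cholesterol synthesis genes had 3 of 10 shortened when adjusted over the list alone and 0 over all genes, with HMGCS1 at 10.7 and 2.60 h. C2H2 zinc finger genes had 0 and 8 of 166, among them ZNF106 (8.68 and 2.04 h), and immediate early genes 2 and 2 of 14, namely CTGF (1.59 ± 0.051 and 0.792 h) and ZFP36L1 (1.11 and 0.797 h). Oxidative phosphorylation, liver metabolism, actin and adhesion and mitochondrially encoded genes had 0 by both counts, and their median changes were -1.84, -0.47, -1.33 and -0.35. For oxidative phosphorylation and for actin and adhesion the camera test pointed to longer half-lives than in other genes although these medians were below that of all genes, and neither list was called. The oxidative phosphorylation median covered 6 genes, and over 49 genes with a decay rate in every column the median rate went from -0.0181 and -0.0138 per h in shNS to 0.0106 and 0.0516 per h in shIGF2BP3, against 0.0569 and 0.0739 to 0.144 and 0.185 per h over all genes, a smaller rise.

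By camera of limma, AU-rich cytokines and growth factors (7 tested) differed from the other genes in shIGF2BP3, with a median change of -0.33 against -0.86 for all genes (adjusted p = 0.0198). The call was lost with an estimated correlation (camera adjusted p = 0.981), in a run on 2 residual degrees of freedom that could call little. It also did not hold in every fit that left out 1 column. CSF1, a macrophage growth factor, was shortened in this list (3.52 ± 0.5 h in shNS and 1.87 h in shIGF2BP3), and NFKBIA was prolonged, with the same 2 genes called when adjusted over the list alone and over all genes. Literature IGF2BP targets had a median change of -1.64 and were not called against other genes (adjusted p = 0.368). By fry of limma, which makes no comparison with other genes, that list moved on balance to shorter half-lives (adjusted p = 0.0351), as did p53 targets, the m6A machinery and ribosome biogenesis genes at the same adjusted p. Of the study targets, MYC mRNA was at 0.745 ± 0.046 h in shIGF2BP3 (0.05, limma adjusted p = 0.605) and FSCN1, whose replicates went opposite ways, at 5.20 and 2.27 h against 1.69 and 44.1 h in shNS (-1.33, limma adjusted p = 0.456). IGF2BP1 mRNA was at 3.04 h in this line (-1.02, limma adjusted p = 0.069).

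A direct contrast of shIGF2BP1 with shIGF2BP3 asks whether the 2 knockdowns differ in their effect. The median half-life ratio was 0.67 on the log2 scale, longer in shIGF2BP1, but 0 genes were called in either direction by limma, with 1826 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0781. Without the replicate block, 7 genes were called shorter-lived and 821 longer-lived in shIGF2BP1 than in shIGF2BP3, while with columns centred on their medians 24 were shorter-lived and 1 longer-lived. The column medians differed by 0.71 (exact permutation p = 0.333). Changes in the 2 lines correlated across genes (r = 0.71, rho = 0.65), where a shared control alone gave r = 0.50 in simulated data. With separate control columns r was 0.21 and 0.19, on single columns, which add noise. Those pairs cross replicate numbers. Deviations of same-numbered columns of the 2 lines correlated at -0.39 (Spearman), so crossed columns may share deviations as well. Immediate early genes, oxidative phosphorylation genes and p53 targets differed between the lines relative to the other genes by camera of limma at the preset correlation. None of the 3 was called with an estimated one (camera adjusted p = 0.760, 0.728 and 0.728), in a run on 2 residual degrees of freedom that could call little. Values of the 3 lists are given among the results for a closer look.

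The last comparison joins half-life and expression across the 5443 genes, both of which draw on the untreated libraries. The Spearman correlation of half-life change with expression difference was 0.20 in shIGF2BP1 and 0.17 in shIGF2BP3. In replicates 1 and 2 alone it was 0.17 and 0.21 in shIGF2BP1, and 0.10 and 0.21 in shIGF2BP3. Among genes with a shorter half-life, 48.4% were lower in expression in shIGF2BP1, against 32.8% of those with a longer one. In shIGF2BP3 the shares were 78.0% and 63.4%. CCNB1 was lower in expression and shorter-lived in shIGF2BP3, while MYC was lower in expression with half-lives of 0.719 h in shNS and 0.745 h in shIGF2BP3.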

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

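Of the tests in this part, those on negative half-lives, on literature IGF2BP targets and on ribosomal protein mRNAs as a zero point were chosen only after the result was seen.

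In 3 gene lists the half-life change differed between shIGF2BP1 and shIGF2BP3 relative to the other genes, by a direct contrast with camera of limma. All genes had a median log2 difference of 0.67, longer in shIGF2BP1. The runs with an estimated correlation rest on 2 residual degrees of freedom and could call little. Estimated correlations were -0.0984 for oxidative phosphorylation and -0.0108 for p53 targets, below the preset 0.01, so they do not explain those lost calls. For immediate early genes the estimate was 0.779. Immediate early genes (14 tested), the fast transcription factors and regulators of a growth stimulus, had a median change of 0.34 in shIGF2BP1 and -0.26 in shIGF2BP3 (limma adjusted p = 0.00104, and adjusted p = 0.760 with an estimated correlation). Their median difference of 0.56 and mean of 0.53 lay below the all-gene median of 0.67 although the test pointed up. The test divides changes by their SE, so it does not show a larger change in this list. When adjusted over the list alone, 11 of the 14 were longer-lived in shIGF2BP1, against 0 over all genes. The call of this list ended without shIGF2BP3 replicate 2. Oxidative phosphorylation genes (6 tested, of 49 with a decay rate) had a median change of -1.64 in shIGF2BP1 and -1.84 in shIGF2BP3, with a median difference of -0.69 (limma adjusted p = 0.00239, and adjusted p = 0.728 with an estimated correlation). Leaving out 1 column at a time gave adjusted p from 0.00288 to 0.0832 by limma, the highest without shIGF2BP3 replicate 2, which ended the call. Genes activated by p53 (22 tested) had a median change of 0.01 in shIGF2BP1 and -0.89 in shIGF2BP3, with a median difference of 0.79 (limma adjusted p = 0.0280, and adjusted p = 0.728 with an estimated correlation), and 10 were longer-lived in shIGF2BP1 when adjusted over the list alone against 0 over all genes. By limma that call ended without shNS replicate 1 (adjusted p = 0.0619), without shNS replicate 2 (adjusted p = 0.0684) and without shIGF2BP3 replicate 2 (adjusted p = 0.176). In the 4 half-life columns of the knockdown lines, list half-lives from the median decay rate were 1.32 and 1.43 h in shIGF2BP1 against 0.797 and 0.766 h in shIGF2BP3 for immediate early genes, and 3.46 and 3.65 h against 1.86 and 1.83 h for p53 targets. For oxidative phosphorylation genes they were 26.3 and 20.3 h against 65.3 and 13.4 h, so the 2 replicates went opposite ways.

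The contrast sits on a wider pattern, shorter half-lives of most genes in shIGF2BP3, which did not come from leaving out genes with a negative half-life, since 85.9% of all genes with a decay rate decayed faster in shIGF2BP3. A single constant added to every decay rate is argued against as the whole of the difference. The median rise was larger in the fastest than in the slowest of 3 groups of genes, by at least 0.0504 per h in each replicate. The slowest group still rose by 0.0465 and 0.0817 per h, so a constant may make up part of the rise. A lower zero point in shNS, read from ribosomal protein mRNAs, is argued against as the whole of the difference, as a rise of 0.0442 per h remained in both replicates of shIGF2BP3 with that zero, although it was smaller than the 0.0861 and 0.105 per h without it, and in shIGF2BP1 no rise was left (-0.00339 and -0.0295 per h). Whether the pattern reflects lost stabilisation of IGF2BP targets stays open. The literature list was not called against other genes (limma camera adjusted p = 0.368), but with 12 tested members this does not show equal shortening. Over its 23 members with a decay rate in every column, the median rate went from 0.0157 and 0.0377 per h in shNS to 0.150 and 0.153 per h in shIGF2BP3. For all genes it went from 0.0569 and 0.0739 to 0.144 and 0.185 per h, a smaller rise in both replicates, though by little in replicate 2. Also open is how fully actinomycin D stopped transcription in each line, which the deposited values do not show. Nor do they show whether the rates are relative to the pool of mapped RNA. In untreated cells 20 abundant genes held an estimated 14.1% of reads in shNS and 32.0% in shIGF2BP3. A loss of mRNA stability in shIGF2BP3 therefore remains a hypothesis that may hold for part of the pattern.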

How the results depend on the processing

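The alternatives that join the decay rate with another choice, the decay rate for gene lists and for the relation with expression, centring without the block, centring for genes shared by all 3 lines, and the crossed pairing were chosen only after the result was seen. For expression, leaving out replicates and the replicate number as a block were not run, because the table holds averages only. Genes and lists named one by one kept direction and side of the threshold in 1250 of the values recomputed, while 113 passed the threshold newly, 173 no longer passed it and 1 reversed. Summary values stayed within their spread or within 1.5 times the count in 122 cases and moved in 91. Except where the construction of an alternative shows it, the cause was not tested.

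Expression counts moved with the threshold. A 1.5-fold difference gave 1995 genes higher and 1752 lower in shIGF2BP1, 2233 and 2674 in shIGF2BP2, and 1059 and 3489 in shIGF2BP3. A pseudocount of 0.1 RPKM, which lets genes near 0 pass, gave 1097 higher and 915 lower in shIGF2BP1 and 1690 lower in shIGF2BP3. At a mean of at least 5 RPKM, with fewer genes, 395 were higher in shIGF2BP1 and 485 in shIGF2BP2, and the Spearman correlations were 0.27 between shIGF2BP1 and shIGF2BP2, 0.41 between shIGF2BP1 and shIGF2BP3 and 0.11 between shIGF2BP2 and shIGF2BP3. The last was 0.15 with a pseudocount of 0.1 RPKM. Centring the columns removes the median of -0.30 in shIGF2BP3 and gave 861 genes higher and 414 lower there and 52 genes lower in all 3 lines, and turned the ribosomal protein list from -0.24 to 0.0588.

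The lower median half-life of shIGF2BP3 kept its direction, at -0.84 with half-lives above 24 h set to 24 h, -0.78 for genes with a mean half-life under 12 h, and -0.91 to -0.78 when 1 column was left out. The count of called genes did not hold in the same way. Without the replicate block, which frees a degree of freedom and is supported by replicate numbers that do not pair the samples, 17 genes were shortened and 12 prolonged in shIGF2BP1, 1775 and 16 in shIGF2BP3, and between the lines 7 were shorter-lived and 821 longer-lived in shIGF2BP1. Of the 456 shortened genes, 454 were among those 1775. In shIGF2BP3 the ceiling of 24 h gave 1135 shortened and 10 prolonged, the mean under 12 h 1159 and 10, and the robust prior 712 shortened. Centred columns gave 16 shortened and 55 prolonged in shIGF2BP1, 13 and 274 in shIGF2BP3, and 24 and 1 between the lines. Centred columns without the block gave 44 and 67, 46 and 315, and 8 and 1. The decay rate called 0 shortened and 0 prolonged in shIGF2BP3 by limma, with 3184 genes at an unadjusted p under 0.05, and again 0 and 0 when centred, but 1176 and 13 without the block. Pairing the shIGF2BP3 replicates with the other table's controls gave 1481 and 14. Fits without 1 column have fewer residual degrees of freedom, so their counts mix that loss with the effect of the column itself. When 1 column was left out, a lone column was assumed to vary like the others, and the counts ranged from 0 to 5 shortened and 0 to 22 prolonged in shIGF2BP1 and from 0 to 515 and 0 to 57 in shIGF2BP3, the highest values each without shNS replicate 2. The 10 named shortened genes of shIGF2BP3 were all called without the block, with the robust prior and with crossed pairing, 7 without shNS replicate 2, 4 when centred, 8 with the decay rate without the block, and 0 with the decay rate and the block or without any other column.

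Of the gene lists, 4 were called in shIGF2BP1, 1 in shIGF2BP3 and 3 between the lines by camera of limma. With an estimated correlation 0 were called in each, for log2 half-life and for the decay rate, in runs on 2 residual degrees of freedom that could call little. In shIGF2BP3, 2 lists were called without the block, 4 with the decay rate and 7 with the decay rate without the block, and between the lines 7 and 8 with the latter choices. Leaving out 1 column gave 1 to 3 lists in shIGF2BP1, 0 to 1 in shIGF2BP3 and 0 to 5 between the lines. The correlation of half-life with expression in shIGF2BP1 was 0.17 in replicate 1 alone and 0.13 with the decay rate. Depth per library is unknown, so what it limits was not assessed, and 2 replicates limit the half-life tests.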

Other observations

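Of the tests in this part, those on decay rates of secreted proteins and on admixed cells were chosen only after the result was seen.

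NFKBIA was longer-lived in both lines, at 0.908 h in shIGF2BP1 and 0.676 h in shIGF2BP3 against 0.548 h in shNS. Only the change in shIGF2BP3 passed the limma test, and it did not pass with the decay rate or when any 1 column was left out. RYBP, a Polycomb subunit, was at 1.25 h in shNS and 3.37 h in shIGF2BP1, and FEZ2 at 1.99 and 7.84 h, both as values that did not pass. The ribosome factor MRTO4 was longer-lived in shIGF2BP3 while the median change of its list, ribosome biogenesis, was -1.05.

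In untreated cells AFP, the fetal counterpart of albumin and a marker of immature and tumour liver cells, was 3174 RPKM in shNS, 2199 RPKM in shIGF2BP1, 3175 RPKM in shIGF2BP2 and 12246 RPKM in shIGF2BP3. HULC, a noncoding RNA of liver cancer, was 15.3 RPKM in shNS, 2.22 RPKM in shIGF2BP2 and 46.3 RPKM in shIGF2BP3. The integrins ITGA2 and ITGA3 were 24.2 and 2.49 RPKM in shNS and 187 and 49.3 RPKM in shIGF2BP2. GAPDH, often used as a reference, was 426 RPKM in shNS and 167 RPKM in shIGF2BP1.

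Hepatocyte genes were higher and the median gene lower in untreated shIGF2BP3. A larger share of reads in a few abundant genes can account for the lower median. Leaving out 20 abundant genes and rescaling moved the median log2 difference from -0.30 to -0.0324. Those genes held an estimated 14.1% of reads in shNS and 32.0% in shIGF2BP3. They were picked by their largest share in any line, shIGF2BP3 included, which favours such a move. GC content and transcript length are argued against for the higher hepatocyte genes, as log2 differences in shIGF2BP3 hardly followed either (Spearman -0.02 and -0.04). The secreted list had a median of 1.91 after that trend was removed, against 1.90 with columns centred, so the removal changed little beyond centring. Longer half-lives of the secreted list could neither be shown nor excluded, since its median decay rate was higher in shIGF2BP3 by 0.0218 per h as deposited but lower by the change of -0.0694 and -0.0852 per h in the 2 replicates when columns were centred. Whether the hairpin or the selection of the line led to the higher hepatocyte genes was not tested.

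In untreated shIGF2BP2, cell cycle and hepatocyte genes were lower while CPA4, ANXA1 and UCA1 were higher. Admixed cells of another type as the only difference would lower all hepatocyte genes by about 1 factor. But 28.6% of the secreted list, 12 of 42 genes with ALB among them, lay at or above shNS while 18 were lower by 2-fold or more. Admixture together with other changes in the line is not excluded, and 3 of 6 markers of other cell types (COL1A1, PDGFRB and ACTA2) were higher by 2-fold or more. GC content and transcript length are argued against, as the mitosis list had a median of -2.40 after that trend was removed. A difference in culture or batch between the lines cannot be tested with averages and stays open, as does a biological effect of IGF2BP2.

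No chromosome's median log2 difference departed from that of all other genes by more than 0.11, the value for chromosome 4 in shIGF2BP1. Chromosome 11 in shIGF2BP1 departed by -0.09 the other way (permutation test over genes, adjusted p = 0.0345 for both chromosomes). That p-value does not measure the spread between libraries. The small size of the departures argues against gain or loss of whole chromosomes between the lines.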
